A study of Homo sapiens with 5 samples.

How the data were processed

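The series holds 5 libraries of single cells made with a 10x Genomics 3' kit, per the labels, from H9 embryonic stem cells before treatment, at 12 h, 24 h and day 4 of BMP4 and IWP2, and from the TSC made from them. The series design gives a target of 1000 cells per library. The authors aligned the reads to GRCh38 and counted UMIs with Cell Ranger 6.0.1, and the deposited tables hold their unnormalized UMI counts for 36601 genes and 566 to 5444 barcodes per library. The annotation release and the strand setting are not given in the sources used here, and genes carry symbols only.

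Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left out 1258 barcodes at t0, 342 at 12 h, 436 at 24 h, 99 at day 4 and 162 in TSC. The cells with the highest Scrublet scores were then removed as doublets, 0.8% per 1000 kept barcodes of a library, which took 140, 16, 136, 2 and 7. UMIs of the kept cells were summed per library and scaled to UMIs per 1000000 UMIs of that library (CPM). Intervals are exact 95% Poisson intervals for levels, exact conditional Poisson intervals for ratios and exact binomial intervals for shares. Intervals of medians by transcript length and of the spread of ribosomal protein genes came from 1000 resamples of the genes. The others hold counting error only, since each group has 1 library and no test between groups could be made.

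The comparisons were 12 h over t0, 24 h over t0 and over 12 h, day 4 over t0 and over 24 h, and TSC over day 4 and over t0. For a library with no UMI, a ratio given as "at least" is the lower limit of its exact interval. List medians, and ratios said to use the floor, set counts under 3 in a library to a floor of 3 counts. Ratios with the floor are not interval limits. With 1 to 3 UMIs the ratio as counted is given with its interval. Gene lists, 26 in number, and the rule for named genes were among the choices made before the data were examined. A list member was measured where it had more than 3 UMIs in either library, and was called where it differed at least 2-fold with an interval that excluded no change. The interval of a list median came from 1000 Poisson redraws of the counts, and its percentile from 10000 random lists matched in 20 expression bins, which describes these libraries and is not a test across cultures.

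Genes were named from those with at least 50 CPM in the higher library and ranked by the interval bound nearest no change. The highest and lowest 12 were taken for day 4 over t0 and TSC over day 4, and 8 each way for 12 h over t0, 24 h over 12 h and day 4 over 24 h. The rule ranked 2465, 2325, 3325, 3191 and 3369 genes in time order. Mitochondrial, ribosomal protein, clone-named and LINC genes were left out of the ranking, and other genes named are members of the lists.

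For shares of cells, each cell was thinned at random to 5000 UMIs, and shallower cells were left out. Clusters used 2000 variable genes, counts scaled to 10000 UMIs per cell, 30 principal components, 15 neighbours and the Leiden method, at resolution 0.5 for all cells together and 0.3 within a library. Clusters were named from marker genes, which define them and are no finding. Transcript lengths came from the GENCODE v29 basic annotation, which matched 20617 of 21486 genes (96.0%) by symbol. Barcode sets were compared by the first 7 bases of the barcodes.

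Alternatives tried were no barcode filter, a strict filter of at least 1500 genes and at most 10% mitochondrial UMIs, no doublet removal, TMM and median-of-ratios scaling, a mean over cells, totals without mitochondrial (13) and ribosomal (103) gene names, a floor of 1 count, members with at least 50 UMIs, and other cluster resolutions (1 and 0.6). A transcript-length correction and cells with at least 5000 UMIs were added after the data were seen. The calls were tested on simulated data. For each pair, both pools were drawn as Poisson counts from the profile of 1 library, with 4-fold changes put into some genes. Such pools hold counting error only, so they check the calculation and do not measure false calls between real libraries. All higher genes and 94% or more of the lower genes were recovered, 0.0897% to 0.420% of unchanged genes were called, and 95.3% to 96.0% of intervals held the true ratio. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.

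Left out were tests between groups, RNA velocity and pseudotime, since each stage is 1 library, and batch correction, since stage and barcode set go together.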

Results

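Single-cell RNA was measured in H9, an established human embryonic stem cell line kept in the primed pluripotent state, before and during treatment with BMP4 and IWP2. BMP4 is a ligand of the bone morphogenetic protein (BMP) pathway, given at 10 ng/mL, and IWP2, given at 2 µM, blocks the secretion of WNT ligands. The 5 libraries were 1 of untreated cells (t0), 1 each at 12 h, 24 h and day 4 of treatment, and 1 of trophoblast stem cells (TSC) that the same line gave when day 4 cells were moved to TSC medium, at passage 6. The labels describe the day 4 cells as trophectoderm-like and state that the large majority carried EGFR protein on their surface by flow cytometry. Each group was 1 library without replicates, so no difference was tested against a spread between cultures, and every bracketed range below is a 95% interval for counting error only, except where it is said to come from resampled genes.

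After filtering, 4046 cells with 49128406 UMIs (unique transcript counts) remained at t0, 1377 with 27536248 at 12 h, 3986 with 50556688 at 24 h, 465 with 9019898 at day 4 and 905 with 32871794 in TSC. The deposited tables held 54256796, 28742306, 53849749, 9258949 and 34098950 UMIs in the same order. The median depth per cell was 10924 UMIs at t0, 16109 at 12 h, 11598 at 24 h, 14782 at day 4 and 33230 in TSC. Mitochondrial transcripts made up 6.61%, 4.76%, 4.17%, 6.62% and 9.45% of the UMIs. The noncoding RNAs MALAT1 and NEAT1, which stay in the nucleus, set the day 4 library apart, with a median of 3.06% of UMIs per cell against 0.28% at t0, 0.42% at 12 h, 0.52% at 24 h and 0.53% in TSC (cells thinned to 5000 UMIs). The barcodes of t0, 12 h and 24 h shared nearly all of their 7-base starts, 473 of the 480 at t0 for 12 h and 480 for 24 h. Day 4 and TSC shared only 54 and 81 of the 480, so comparisons of either with the earlier libraries also crossed a difference in barcode set, and stage and set cannot be told apart there. With each other they shared 294 starts, of 428 at day 4 and 640 in TSC, a weaker overlap than among the earlier libraries. Day 4 and TSC are treated as 1 set below. Genes were identified by symbol alone, as in the deposited tables. A gene is called higher or lower where its pooled level, in UMIs per 1000000 UMIs of a library (CPM), differed by at least 2-fold with an interval that excluded no change.

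The first comparison, 12 h against t0, asked how cells at 12 h of BMP4 and IWP2 differed from untreated cells. The libraries included no untreated culture at 12 h, 24 h or day 4. In every comparison with t0, treatment and time in culture therefore cannot be told apart. Direct targets of BMP signalling were the clearest group: 12 of the 14 measured members of the BMP response list were higher and none was lower, with a median log2 ratio of 3.66 [3.60, 3.89]. The inhibitors of differentiation ID1, ID2 and ID4 were 10.8-fold [10.6, 11.1], 14.4-fold [13.3, 15.5] and 15.9-fold [14.5, 17.5] higher, and the BMP pseudoreceptor BAMBI was 11.2-fold [10.6, 11.8] higher. GATA3, a transcription factor of the trophoblast lineage, went from 1.28 to 70.9 CPM, a ratio of 55.3 [43.0, 72.2]. POU5F1, the core pluripotency factor, stayed at 778 CPM against 754 at t0.

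Of the 19 measured members of the trophectoderm list, 8 were higher, 11 neither and none lower (median 0.67 [0.54, 0.92]), among them GATA2 with a ratio of 70.3 [41.6, 129.5] and TFAP2A with 131 [66.1, 305]. HAND1 was at 1.60 CPM at 12 h and had no UMI at t0, 26.2-fold higher with the floor of 3 counts at t0. KRT7 was not called higher, and VGLL1 had no UMI in either library. MSX2, a homeobox target of BMP, was 232-fold [122, 508] higher, and the secreted BMP antagonist NOG had 401 UMIs against 3 at t0, a ratio of 238 [81.0, 1161].

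The pluripotency list had a median of -0.55 [-0.59, -0.51], with 6 members lower, 1 higher and 13 neither. Expression-matched random lists centred on a median of -0.20, so genes of like expression were lower too, though by less. The DNA methyltransferase gene DNMT3B was 2.98-fold [2.89, 3.06] lower, the NODAL co-receptor gene TDGF1 2.19-fold [2.14, 2.25] lower and the NODAL antagonist gene LEFTY1 3.89-fold [3.56, 4.26] lower. GDF3 was 2.85-fold [2.63, 3.09] higher. NODAL itself was 2.16-fold [1.91, 2.44] lower, although the list of NODAL and TGF-beta targets had 3 members each way and a median of 0.19 [-0.03, 0.23]. AXIN2, a feedback target of WNT signalling, was 3.74-fold [2.62, 5.46] lower, while the WNT target list as a whole had 2 members higher and 1 lower (0.67 [0.10, 1.10]).

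Among genes at 50 CPM or more in the higher library, ranked by the interval bound nearest no change, those highest at 12 h besides GATA3 and the BMP targets were the noncoding gene PCAT14, 65.0-fold [57.8, 73.5] higher, RHOBTB3, 11.9-fold [10.3, 13.9], and the cardiac actin gene ACTC1, 7.67-fold [7.17, 8.21]. The lowest in the same ranking were the interferon-inducible IFITM1, 30.2-fold [23.0, 40.6] lower, and the homeobox gene HESX1, 8.18-fold [7.10, 9.45]. ARF5, FZD7, AK4 and SLC29A1 were 3.67-fold to 5.68-fold lower. None of the 41 S phase genes and none of the 51 G2M phase genes was called either way, with medians of -0.13 [-0.23, -0.09] and 0.03 [-0.01, 0.07]. The FGF and ERK target list had no called member among 15 (median -0.24 [-0.29, -0.12]). The epithelial list had 1 of 12 lower (-0.52 [-0.57, -0.39]).

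The t0 library differed from 12 h and 24 h in short ribosomal protein mRNAs. The 33 ribosomal protein genes with transcripts under 700 bases had a median log2 ratio of 0.72 [0.52, 1.05] at 12 h over t0 (intervals in this paragraph from resampled genes), and the 46 longer ones had 0.05 [-0.08, 0.12]. At 24 h over t0 the values were 0.40 [0.30, 1.07] and -0.20 [-0.29, -0.08].

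**Figure D1:**
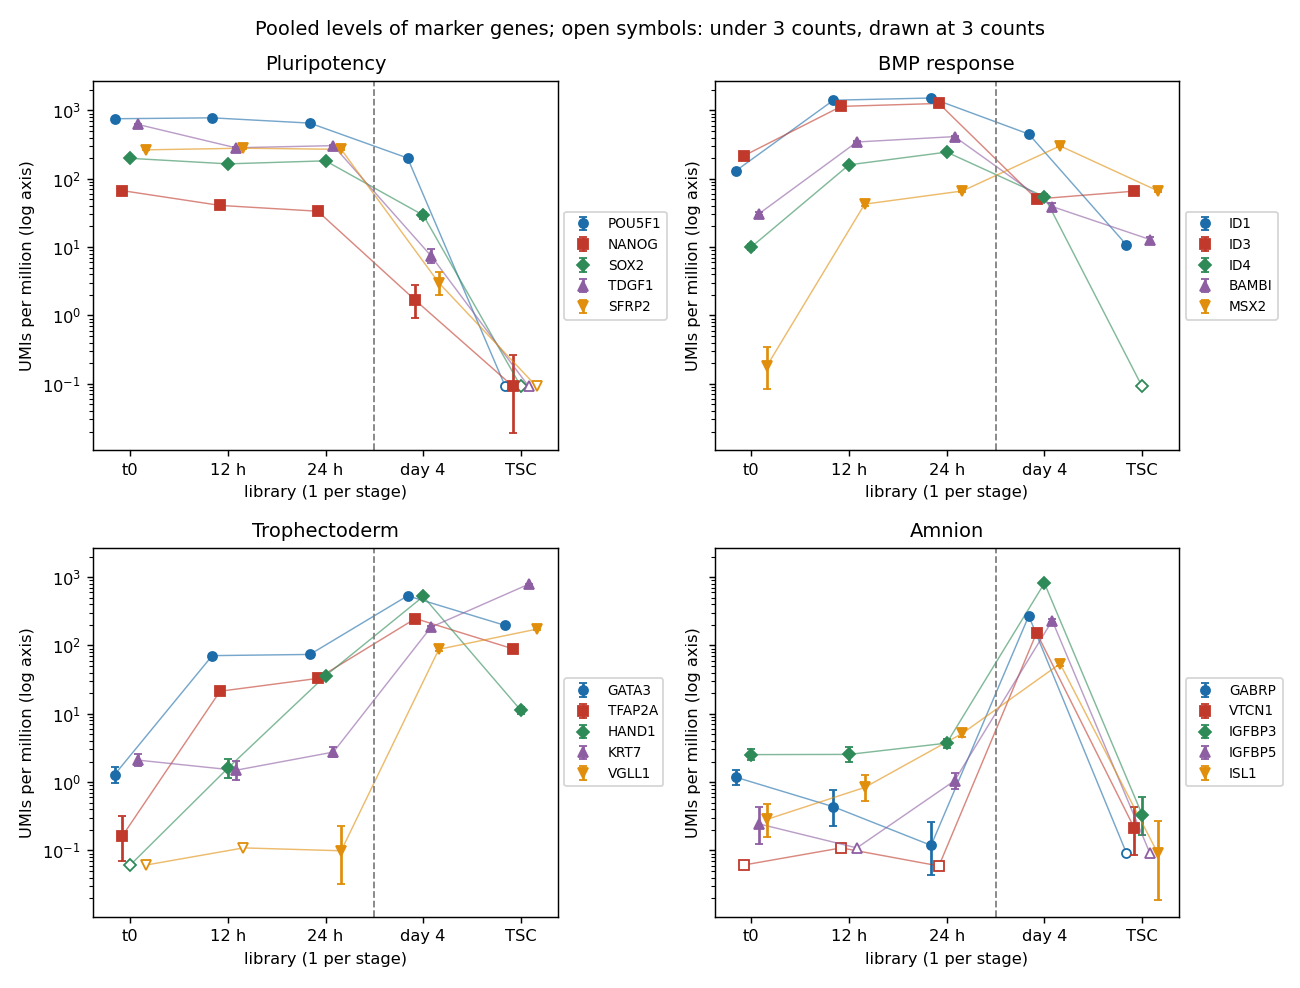
Pooled CPM (log axis) of 5 marker genes per panel in each of the 5 libraries, with 95% Poisson intervals as bars, open symbols for genes under 3 counts drawn at 3 counts, and a dashed line between the 2 barcode sets. The BMP targets shown were higher at 12 h and 24 h than at t0, and the amnion markers shown were highest at day 4.

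At 24 h the BMP response was close to its 12 h level. The BMP response list had a median of 0.12 [0.07, 0.15] over 12 h, with 1 of 14 members higher, and 3.92 [3.76, 4.08] over t0, with 13 higher. The trophectoderm list had 2 of 20 members higher than at 12 h, 18 neither and none lower (0.52 [0.31, 0.65]). It reached 1.31 [1.10, 1.38] over t0, with 11 of 20 members higher, 9 neither and none lower, at percentile 100 among 10000 expression-matched random lists. HAND1 was 22.5-fold [16.7, 31.1] higher than at 12 h, while GATA3 was level at 1.04-fold [0.985, 1.10]. The ligand gene BMP4 itself was 5.11-fold [4.67, 5.61] higher than at 12 h and 32.9-fold [27.9, 39.1] higher than at t0.

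Amnion genes were higher over 12 h in 6 of 12 measured members, lower in 1 and neither in 5 (0.92 [0.62, 1.77]). They included ISL1, a LIM homeobox factor of the amnion, at 6.18-fold [4.03, 9.92], and DLX5 at 3.49-fold [2.22, 5.75]. Extravillous trophoblast genes were higher than at t0 in 7 of 17 measured members and lower in 2 (0.96 [0.68, 1.27]). Over 12 h, 2 of 16 were higher, 1 lower and 13 neither (0.27 [0.04, 0.52]). The fibronectin gene FN1 was 5.45-fold [4.97, 5.98] and the prostaglandin dehydrogenase gene HPGD 4.11-fold [3.82, 4.42] higher. The other genes highest over 12 h were ANKRD1 at 5.93-fold [5.44, 6.47], the claudin gene CLDN10 at 5.12-fold [4.96, 5.30], RHOBTB3 at 4.10-fold, SPP1 at 3.77-fold and the neurotensin gene NTS at 3.39-fold [3.35, 3.44].

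Metallothioneins, which bind zinc and copper, had the lowest median of the 26 lists at 24 h over 12 h, with 3 of 7 members lower, none higher and a value of -0.94 [-1.10, -0.87]. At 12 h over t0, 2 of the 7 had been higher and none lower (0.82 [0.78, 0.97]), and at 24 h over t0 none was higher and 1 lower (0.06 [-0.15, 0.16]). MT1E, MT1G and MT1X were 2.64-fold [2.45, 2.85], 2.38-fold [2.28, 2.48] and 2.15-fold [2.11, 2.20] lower, and MT1H was 1.92-fold [1.83, 2.01] lower, short of the 2-fold bound. These genes are near-identical copies, so the share of each copy is uncertain. LRRC75A was 3.72-fold [3.48, 3.97], C1orf56 2.21-fold and the WNT antagonist gene SFRP1 2.05-fold [1.91, 2.21] lower, and EIF3L was at 1.97-fold. No member of the pluripotency list was called between 12 h and 24 h (median 0.05 [0.00, 0.09], and -0.03 with mitochondrial and ribosomal genes out of the total). NANOG was at 33.4 CPM at 24 h against 66.9 at t0, 2.00-fold [1.89, 2.12] lower. The cholesterol synthesis list had a median of -0.38 [-0.44, -0.31] over 12 h with no called member among 16.

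The comparison of day 4 with t0 asked whether the treated cells had taken on a trophectoderm programme. Trophectoderm genes were higher in 19 of the 20 members and lower in none, with a median log2 ratio of 5.63 [5.45, 5.80]. GATA3 reached 532 CPM, 415-fold [324, 541] above t0, and the keratin genes KRT7, KRT8, KRT18 and KRT19 were 88.2-fold [72.3, 109], 13.7-fold [13.3, 14.1], 4.59-fold [4.51, 4.67] and 34.4-fold [33.1, 35.7] higher. EGFR, the receptor named in the labels, was 26.4-fold [20.5, 34.4] higher. Pluripotency genes were lower in 15 of 20 members and higher in none (median -2.47 [-3.12, -2.34]). NANOG was 40.3-fold [24.4, 72.0] lower, SOX2 6.79-fold [6.01, 7.70] and POU5F1 3.76-fold [3.58, 3.94], which left POU5F1 at 201 CPM.

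Genes of the amnion were higher in all 14 of the measured members, with a median of 7.54 [7.34, 7.83], which exceeded the trophectoderm median. Both medians are ratios to t0 and do not compare the levels of the lists at day 4. IGFBP3 and IGFBP5, which bind insulin-like growth factors, were 323-fold [270, 389] and 945-fold [539.6, 1831] higher. The GABA receptor subunit gene GABRP was 229-fold [177, 303] and ISL1 189-fold [112, 349] higher. VTCN1 went from no UMI to 153 CPM, at least 2036-fold. Only 1 of the 15 amnion genes belongs to another list, against 6 of the 20 trophectoderm, 7 of the 20 cytotrophoblast and 2 of the 20 pluripotency genes. With a floor of 1 count in place of 3 the amnion median was 8.58.

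Cytotrophoblast and syncytiotrophoblast genes were also higher. Of 20 cytotrophoblast genes, 18 were higher and 1 was lower (3.75 [3.40, 4.10]), among them the retroelement-derived PEG10 at 66.9-fold [64.1, 70.0]. TP63, a factor of trophoblast progenitors, went from no UMI to 6.32 CPM, 103-fold with the floor at t0. The integrin gene ITGA6 was 2.27-fold [1.94, 2.68] lower. Of 14 measured syncytiotrophoblast genes, 10 were higher and none lower (6.78 [6.37, 7.13]). CGA, the shared subunit of the glycoprotein hormones, had 1568 UMIs against 2, a ratio of 4270.2 [1180.1, 35291]. GCM1, which drives trophoblast fusion, went from no UMI to 57.1 CPM, 935-fold with the floor at t0. The aromatase gene CYP19A1 was 99.5-fold [62.7, 167] higher. Extravillous trophoblast genes were mixed, with 8 of 17 higher and 2 lower (1.15 [0.67, 1.71]). HLA-G, a marker of that lineage, was at 2.66 CPM.

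Other named genes with the highest ratios at day 4 had few or no UMIs at t0. HAND1 and the keratin gene KRT16 had none, and were at least 6922-fold and at least 3061-fold higher. VGLL1, a cofactor of TEAD factors, and the nucleotide receptor gene P2RY6 were at least 1165-fold and at least 823-fold higher. The orphan nuclear receptor gene NR2F2 had 1893 UMIs against 1, a ratio of 10311 [1848.3, 407460], and the iron exporter gene SLC40A1 1469 against 1, a ratio of 8001.2 [1433.8, 316240]. TBX3, MSX2 and TFAP2A had ratios of 2769 [946, 13441], 1648 [867, 3609] and 1518 [769, 3521]. LCMT1-AS2 had 1966 UMIs against 2, and since it is an antisense gene and the strand setting is not stated, its count is uncertain.

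Of the 12 genes ranked lowest at day 4, 3 were metallothioneins and 4 were members of the pluripotency list. All 7 metallothioneins were lower than at t0, with a median of -6.59 [-6.65, -6.00]. MT1X was 1523-fold [595, 5590] and MT1G 250.4-fold [97.8, 919] lower, and MT1H had no UMI at day 4, at least 181-fold lower. LEFTY1 had 1 UMI against 3812, a ratio of 699.88 [125.54, 27651]. The galanin gene GAL was 124-fold [94, 167] lower, TDGF1 83.8-fold [66.0, 108], SFRP2 88.4-fold [60.7, 134], HESX1 139-fold [54.3, 511], VRTN 116-fold [49.5, 357], USP44 68.7-fold [48.9, 99.8] and CNMD 73.3-fold [47.9, 118]. FOXD3-AS1, also antisense, was 95.8-fold [64.9, 148] lower.

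Targets of BMP, of NODAL and TGF-beta, and of FGF and ERK signalling had shifted by day 4. BMP response genes were higher than at t0 in 12 of 14 members and lower in 1 (3.41 [3.07, 3.73]), but ID3 was 4.27-fold [3.89, 4.70] lower than at t0. NODAL and TGF-beta targets were lower in 8 of 12 members and higher in 3 (-1.83 [-2.00, -1.74]). FGF and ERK targets were lower in 9 of 15 and higher in 4 (-1.55 [-1.78, -1.22]), with the ETS factor genes ETV4 and ETV5 27.7-fold [17.0, 48.5] and 17.2-fold [10.7, 29.6] lower. WNT targets were higher in 5 of 10 and lower in 1 (1.62 [1.26, 2.46]), while AXIN2 was 2.00-fold [1.29, 3.26] lower. The WNT median was at percentile 95.15 among expression-matched random lists. It lay inside their central 95%, -0.73 to 1.88, so no shift of this list stood out.

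Among other lineages, stromal genes were higher in 7 of 9 and lower in 1 (3.24 [2.77, 3.66]). They were led by the proteoglycan gene LUM, from no UMI to 24.6 CPM, 403-fold with the floor at t0. Endoderm genes were higher in 4 of 8 and lower in 2 (1.43 [0.91, 2.03]), primitive streak and mesoderm genes higher in 3 of 11 and lower in 4 (-0.25 [-0.66, 0.86]), and neural ectoderm genes higher in 1 of 10 and lower in 2 (0.39 [-0.14, 1.20]). Epithelial genes were higher in 6 of 12 (1.00 [0.92, 1.08]), with the E-cadherin gene CDH1 5.12-fold [4.79, 5.47] higher. EMT and mesenchymal genes were higher in 5 of 12 and lower in 1 (0.85 [0.42, 1.74]). Imprinted genes were higher in 6 of 10 and lower in 2 (2.02 [1.42, 2.62]). CDKN1C was 180.5-fold [163, 200.3] higher and SNRPN 3.93-fold [3.79, 4.09] lower. Targets of p53 were higher in 9 of 14 and lower in 1 (1.14 [1.03, 1.34]), with CDKN1A 10.4-fold [9.19, 11.8] and GDF15 39.7-fold [32.8, 48.4] higher. Heat shock and dissociation genes were higher in 8 of 12 (1.33 [1.15, 1.56]).

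S phase genes were lower in 13 of 41 and higher in 1 (-0.58 [-0.73, -0.45]), and G2M phase genes lower in 14 of 51 and higher in 2 (-0.29 [-0.46, -0.23]). Lists whose members went both ways were HLA class I and antigen presentation (3 higher and 3 lower of 12, -0.07 [-0.44, 0.23]), cholesterol synthesis (2 and 4 of 16, -0.39 [-0.47, -0.30]), glycolysis and hypoxia (6 and 2 of 16, 0.50 [0.42, 0.72]) and the integrated stress response (6 and 2 of 15, 0.43 [0.14, 0.97]). The median over all genes was 0.49 at day 4 over t0, and TMM scaling shifted every log2 ratio there by -0.46, which turned the stress response median to -0.03 and the neural ectoderm median to -0.07. The primitive streak median became 0.34 when every cell was weighted equally, and the HLA median 0.02.

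**Figure D2:**
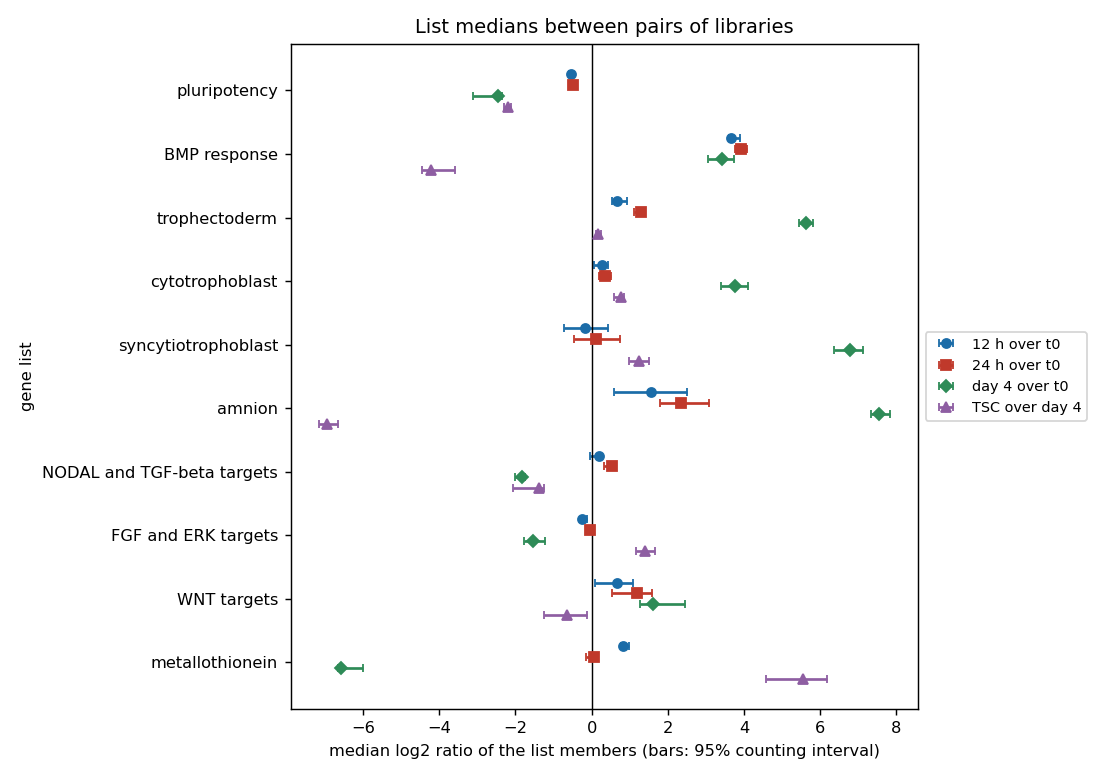
Median log2 ratio of the measured members of 10 gene lists (x axis) for 4 pairs of libraries, with 95% counting intervals as bars. At day 4 over t0 the amnion list (7.54) lay above the trophectoderm list (5.63), as ratios to t0 and not as levels at day 4. From day 4 to TSC the amnion list had the lowest median of the 10 (-6.94).

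Against 24 h, 19 of 20 trophectoderm genes were higher (3.55 [3.47, 3.65]), as were 17 of 20 cytotrophoblast genes (3.62 [3.08, 3.93]), 11 of 14 syncytiotrophoblast genes (5.67 [5.46, 6.56]) and 12 of 14 amnion genes (6.36 [5.76, 6.92]), with none lower in these lists. Extravillous trophoblast genes were higher in 8 of 16 and lower in 4 (0.50 [0.16, 1.36], and -0.06 with TMM scaling). GABRP was 2278-fold [1045, 6215] and the hypoxia-inducible factor gene EPAS1 1003-fold [754, 1367] higher. The genes KRT16, VTCN1, HOPX and XAGE2 had 1 or 2 UMIs at 24 h, with ratios of 5815.2 [1608, 48050], 3870.3 [1069, 31990], 4697 [841, 185740] and 3704.9 [663, 146550]. LCMT1-AS2 had 5, with a ratio of 2204 [943, 6795], and FYB1 none, at least 708-fold.

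On the other side, 13 of 20 pluripotency genes were lower than at 24 h and none was higher (-2.17 [-2.35, -2.09]). SFRP2 was 89.9-fold [61.7, 136], NTS 50.4-fold [46.2, 55.2], GAL 49.9-fold [37.8, 67.2] and MIR302CHG, the host of a microRNA cluster of pluripotent cells, 48.2-fold [45.2, 51.4] lower. GDF3 had 1 UMI against 2975, a ratio of 530.8 [95.2, 20971]. BMP response genes went both ways, 4 higher and 6 lower of 14 (-0.31 [-0.48, -0.16]). MT1X was 760.3-fold [297, 2791], MT1G 181-fold [70.7, 665] and MT1H at least 165.5-fold lower. The median over all genes was 0.54 in this pair, where TMM scaling shifted every log2 ratio by -0.56.

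The comparison of TSC with day 4 asked how stem cells grown in TSC medium differed from the trophectoderm-like cells they came from. Amnion genes were lower in 13 of 15 members and higher in 1, with a median log2 ratio of -6.94 [-7.15, -6.66]. GABRP and IGFBP5 had no UMI in 32871794, at least 2408-fold and at least 2054-fold lower, and IGFBP3 was 2434-fold [1360, 4878] lower. Cytotrophoblast genes were higher in 7 of 20 members, lower in 3 and neither in 10 (0.78 [0.58, 0.86], percentile 99.99 among matched random lists). The integrin genes ITGB4 and ITGA6 were 15.8-fold [11.8, 21.4] and 4.27-fold [3.64, 5.03] higher, and KRT7, also in the trophectoderm list, 4.26-fold [4.05, 4.47] higher. Trophectoderm genes went both ways, 5 higher and 6 lower of 20 (0.17 [0.10, 0.24]), with the surface glycoprotein gene TACSTD2 18.7-fold [14.9, 23.7] higher and HAND1 46.4-fold [41.8, 51.8] lower.

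Pluripotency genes were lower again, in 14 of 16 measured members with 1 higher (-2.19 [-2.30, -2.11]). POU5F1 had 2 UMIs against 1810, a ratio of 3298 [912, 27255], and MIR302CHG had none, at least 924-fold lower. BMP response genes were lower in 12 of 14 and higher in none (-4.22 [-4.45, -3.57]). ID1 was 41.8-fold [37.5, 46.7] and ID2 603-fold [345, 1169] lower. The TSC medium contained the BMP antagonist Noggin, per the labels. FGF and ERK targets were higher in 9 of 15 and lower in none (1.41 [1.18, 1.67]), with ETV4 37.3-fold [22.9, 65.4], the phosphatase gene DUSP4 29.7-fold [15.6, 65.2] and the cyclin gene CCND1 12.2-fold [10.6, 14.0] higher. The medium also held FGF2 and EGF.

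The same medium held CHIR99021, which activates WNT signalling through GSK3. WNT targets were higher in 1 of 10 measured members, lower in 3 and neither in 6, with a median of -0.66 [-1.25, -0.13] at percentile 30.2 among matched random lists. AXIN2 was 3.23-fold [2.09, 5.25] higher, TNFRSF19 3.12-fold [2.30, 4.22] lower and NOTUM 2.02-fold [1.40, 2.89] lower. With only members of at least 50 UMIs the WNT median was -0.039, so the list had no clear direction.

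The syncytiotrophoblast list was higher in 10 of 18 measured members and lower in 5 (1.246 [0.99, 1.51]), with CGA 2.56-fold [2.43, 2.70] and the steroid enzyme gene HSD3B1 7.46-fold [5.87, 9.63] higher. GCM1, ERVFRD-1, which encodes a fusogen, and OVOL1 were 55.2-fold [39.0, 80.6], 12.4-fold [9.94, 15.5] and 15.4-fold [13.1, 18.3] lower. CGB3, CGB5 and CGB8 were higher, with no UMI at day 4, but these copies share reads. Extravillous trophoblast genes were lower in 9 of 17 and higher in 3 (-1.02 [-1.64, -0.67]). The transcription factor gene ASCL2 was 47.9-fold [23.2, 119] and HLA-G 6.13-fold [4.07, 9.65] higher, and FN1 27.7-fold [24.8, 31.1] lower.

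Metallothioneins were higher in TSC than at day 4 in 6 of 7 members (5.55 [4.58, 6.19]). MT2A was 174-fold [118, 269] higher, and MT1E had 10705 UMIs against 1, a ratio of 2937.4 [527.1, 116030]. Other genes highest in TSC were GNG11, with 13973 UMIs against 2 and a ratio of 1917 [531, 15831], the galectin gene LGALS1 at 40.6-fold [37.4, 44.2] and the epithelial 14-3-3 gene SFN at 44.2-fold [35.6, 55.5]. SIGLEC6, a sialic acid receptor of trophoblast, was 87.7-fold [50.1, 170] higher, TFPI2 152-fold [89.0, 286], ADIRF 292-fold [99.9, 1418], TNNT3 100-fold [42.8, 308] and ITIH5 71.3-fold [36.1, 165]. SIGLEC5 and the noncoding UCA1 had no UMI at day 4 and were at least 263-fold and at least 197-fold higher.

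Genes lowest in TSC besides those above were the chemokine gene CXCL14, at least 1731-fold, IGFBPL1, at least 715-fold, SPARCL1, at least 664-fold, and the scavenger receptor gene ACKR3, at least 512-fold. KRT16 was 2521-fold [861, 12233] and the activin antagonist gene FST 1682-fold [772, 4589] lower, and PCAT14 had 1 UMI against 961, a ratio of 3502 [627, 138470]. EMT and mesenchymal genes were lower in 7 of 10 and higher in none (-3.37 [-4.56, -2.23]), with the vimentin gene VIM 120-fold [80.5, 186] lower. Stromal genes were lower in 6 of 9, yet the collagen gene COL1A2 was 6.31-fold [5.90, 6.75] higher (-4.62 [-5.23, -3.48]). NODAL and TGF-beta targets were lower in 4 of 8 and higher in 2 (-1.38 [-2.06, -1.25]).

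In TSC, 10 of 41 S phase genes were higher and 31 neither (0.57 [0.48, 0.70]), and 11 of 51 G2M phase genes were higher and 40 neither (0.59 [0.54, 0.66]), with none lower in these lists. Among imprinted genes, 2 of 9 were higher and 2 lower (0.08 [-0.02, 0.15]), H19 by 8.43-fold [7.64, 9.33] higher and CDKN1C by 9.47-fold [9.16, 9.79] lower. Glycolysis and hypoxia genes were lower in 6 of 16 and higher in 2 (-0.76 [-1.01, -0.48]), and p53 targets lower in 5 of 14 and higher in 1 (-0.58 [-0.72, -0.41]). Medians were 0.22 for epithelial, 0.20 for HLA, -0.04 for cholesterol synthesis, 0.03 for heat shock and dissociation and -0.29 for integrated stress response genes. Endoderm (-1.51) and neural ectoderm (-2.28) genes were lower in 3 of 6 and 4 of 7 members. The primitive streak and mesoderm median was -1.31 [-2.36, -0.39] with 3 of 9 members higher and 5 lower, and turned to 1.91 when members under 50 UMIs were left out. The cholesterol median turned to 0.24 with TMM scaling, the heat shock median to -0.08 with every cell weighted equally, and the imprinted median to -0.07 with the transcript-length trend taken off. The median over all genes was -0.28, and TMM scaling shifted every log2 ratio here by 0.28. The amnion median was -8.36 with a floor of 1 count and -6.23 with a strict barcode filter.

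Set against t0, TSC were lower in every pluripotency gene and higher in most trophectoderm, cytotrophoblast and syncytiotrophoblast genes. All 20 pluripotency genes were lower (-6.30 [-6.67, -5.89]), while 19 of 20 trophectoderm genes (5.98 [5.84, 6.15]), 15 of 20 cytotrophoblast genes (5.58 [5.33, 5.80]) and 17 of 20 syncytiotrophoblast genes (5.02 [4.82, 5.39]) were higher, with 1 lower in the last list. KRT7 stood at 787 CPM, KRT18 at 7889 and PEG10 at 5366. Extravillous trophoblast genes were higher in 9 of 18 measured members and lower in 4 (0.86 [0.29, 1.52]). Amnion genes had no common direction, with 5 higher and 4 lower of 11 measured members (-0.74 [-1.22, 0.09]). BMP response genes were lower than at t0 in 8 of 14 members and higher in 3 (-1.18 [-1.43, -0.99]). TMM scaling shifted the log2 ratios of this pair by -0.18.

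Shares of cells with at least 1 UMI were compared after every cell was thinned to 5000 UMIs, which left out 550, 269, 579, 35 and 13 shallower cells from t0 to TSC. A POU5F1 UMI was found in 97.1% [96.5, 97.7] of cells at t0, 94.6% [93.8, 95.3] at 24 h, 54.2% [49.3, 59.0] at day 4 and 0.112% [0.00284, 0.623] in TSC. Free RNA in the day 4 library itself was not measured, and TSC, with 2 POU5F1 UMIs in all, give no measure of it. Without thinning the day 4 share was 79.4% and the TSC share 0.221%, at median depths of 14782 and 33230 UMIs. NANOG was found in 29.9% [28.4, 31.5] of t0 cells and 1 of 430 day 4 cells. ID1 went from 45.3% [43.6, 47.0] at t0 to 93.4% [91.8, 94.8] at 12 h.

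GATA3 was found in 30.2% [27.5, 33.0] of cells at 12 h, 25.7% [24.3, 27.2] at 24 h and 75.8% [71.5, 79.8] at day 4, against 0.601% [0.372, 0.917] at t0, which likewise gives no measure of free GATA3 RNA in the later libraries. The unthinned shares were 51.0%, 43.3%, 89.9% and 1.48%. HAND1 was found in 10.3% [9.33, 11.4] of cells at 24 h and 64.2% [59.5, 68.7] at day 4, and in 0 of 3496 at t0, an interval of up to 0.105% of cells with a UMI at this depth. KRT7 was found in 46.7% [41.9, 51.6] of day 4 cells and 95% [93.3, 96.3] of TSC, against 0.944% at t0. Unthinned, these shares were 66.0%, 99% and 2.42%. EGFR RNA was found in 15.6% [12.3, 19.4] of day 4 cells and 32.6% [29.6, 35.8] of TSC, against 0.744% at t0, and unthinned in 40.9%, 86.3% and 1.75%. These shares are of RNA detection and cannot be set against the surface protein named in the labels.

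IGFBP3 and GABRP were found in 66.5% [61.8, 71.0] and 52.3% [47.5, 57.1] of day 4 cells, and in 0.224% and 0 of 892 TSC cells, an interval of up to 0.413%. Their unthinned shares at day 4 were 71.2% and 63.7%. CGA was found in 7.44% [5.15, 10.3] of day 4 cells against 0 of 3496 at t0, and in 14.8% without thinning. In TSC, a CGA UMI was found in 39 of 892 thinned cells. TBXT, SOX17 and PAX6, markers of mesoderm, endoderm and neural ectoderm, were found in 0 of 430 day 4 cells each, an interval of up to 0.854% with a UMI at this depth, and in 0.117% of cells or fewer in the other libraries.

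**Figure D3:**
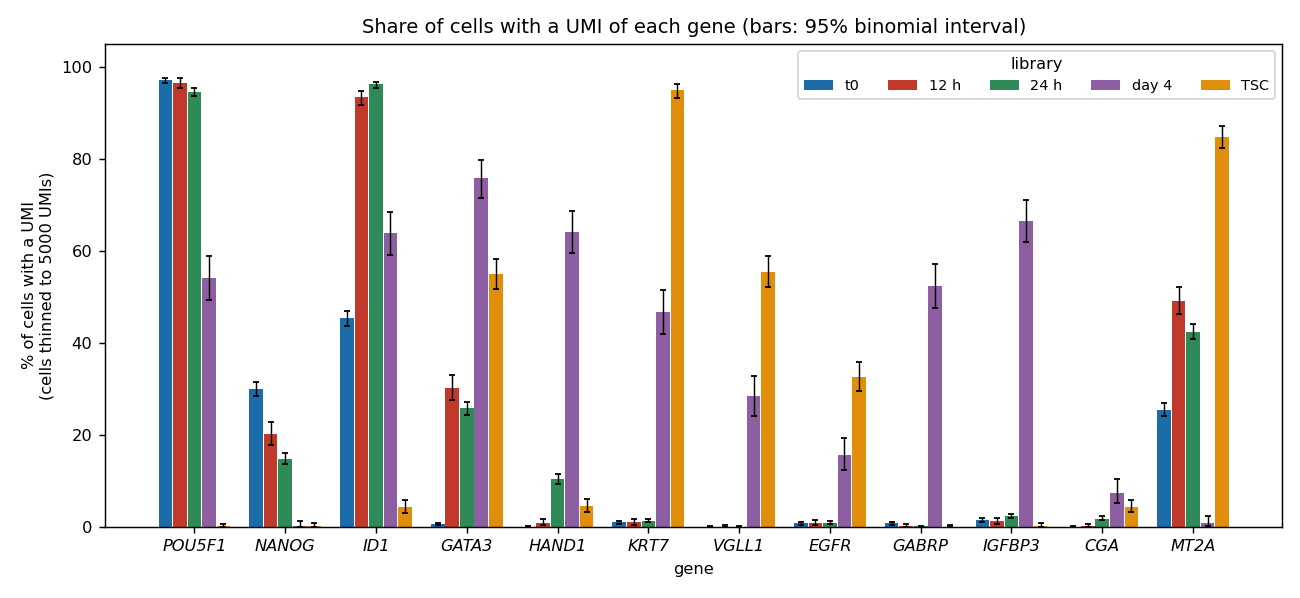
Percent of cells with at least 1 UMI of 12 genes in each of the 5 libraries after thinning to 5000 UMIs per cell, with 95% binomial intervals as bars. POU5F1 was still found in 54.2% of day 4 cells, and GABRP and IGFBP3 were found mostly at day 4.

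In a joint clustering of all cells, stages stayed apart except for 12 h and 24 h. Clusters led by t0 held 98.7% [98.3, 99] of t0 cells, 0.363% [0.118, 0.845] of 12 h cells and 0.878% [0.612, 1.22] of 24 h cells. One cluster held 457 of the 465 day 4 cells and no cell of another library, and all 905 TSC cells lay in clusters led by TSC. A cluster of 1 library can be that library rather than a cell state, and no batch correction was applied.

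Clustered alone, the day 4 library gave 3 groups. The 1st, 192 cells or 41.3% [36.8, 45.9], had VIM as its first gene and was defined by the amnion markers GABRP, VTCN1, IGFBP5, IGFBP3, HEY1, CDH10, ITGB6 and TNC, by the stromal genes COL1A1, LUM, PDGFRB, ACTA2 and COL6A3, and by HAND1, MMP2, FN1, ADAM19 and STMN2. It is called amnion-like after 8 of the 15 amnion markers, although 5 of the 10 stromal markers defined it too. The 2nd, 138 cells or 29.7% [25.6, 34.1], was defined by CGA, ERVFRD-1, LGALS16, OVOL1 and CYP19A1 and is called syncytiotrophoblast-like. The trophectoderm genes GATA2, GATA3, TFAP2C, VGLL1, TEAD3, DAB2 and PGF and the cytotrophoblast genes ITGB4, NR2F2 and IGF2 defined this cluster too. So did NOTUM, HTRA4, TNFRSF1B and APOA2 of other lists. The median depth of the 2nd group was 25821 UMIs against 14782 in the library. Even without thinning, fewer day 4 cells had a CGA UMI than lay in this group, so not all of its cells carried one. The 3rd, 135 cells or 29% [24.9, 33.4], was defined by POU5F1, SOX2, DPPA4, TDGF1, FGF2 and TERF1 of the pluripotency list, together with the amnion markers ISL1, DLX6 and BMP4, and with TACSTD2, GATA6, PRDM1, OTX2 and TUBB3 of other lists. At resolution 0.6 the cluster highest in CGA held 8.82% and the one highest in GABRP 27.3%, so the sizes depended on the resolution. A further cluster there, 97 cells or 20.9%, had GCM1 and HSD3B1 as markers but LGALS16 and HOPX among its lowest genes. At 24 h a cluster of 930 cells, 23.3% [22.0, 24.7], was defined by HAND1, GATA2, GATA3 and ISL1.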

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

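Of 88 alternative values for the 8 main list medians, 75 stayed within the interval of the value reported, 13 moved outside it and none changed sign. Their counts of members stayed within 1.5 times in all 88. The pluripotency median at day 4 over t0 ranged from -2.92 to -2.35. TMM scaling gave 5.17 for trophectoderm and 7.09 for amnion at day 4 over t0, 1.41 for trophectoderm at 24 h over t0 and 1.06 for cytotrophoblast at TSC over day 4. Median-of-ratios scaling gave 5.23, 7.15 and, for cytotrophoblast, 1.02. With members of at least 50 UMIs, trophectoderm at day 4 over t0 was 5.32, BMP response at 12 h over t0 3.92 and WNT targets at TSC over day 4 -0.039, and the primitive streak and mesoderm median at TSC over day 4 turned from -1.31 to 1.91. A floor of 1 count gave 8.58 for amnion at day 4 over t0 and -8.36 at TSC over day 4, and the strict filter gave -6.23 there and kept 534 TSC cells of 905. At resolution 0.6 the clusters highest in HAND1 at 24 h, in CGA at day 4, in GABRP at day 4 and in CGA in TSC held 20.2%, 8.82%, 27.3% and 10.3% of cells. Scaling shifts every gene alike, fewer members and another floor change what enters a median, and for the rest the cause was not tested. Of 174 other list medians, 35 changed sign under some setting, all from values of 1.31 or less in size. Of the 96 named gene ratios, 0 changed sign, but these genes were picked for extreme ratios, so this was nearly fixed by the choice. The transcript-length correction and the 5000 UMI minimum were chosen after seeing the data. No paired analysis was possible because each group has replicate 1 only. The day 4 library had the fewest cells, 465, and the fewest UMIs, 9019898, although its cells were not the shallowest (median 14782 UMIs).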

Other observations

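Chosen after the result was seen were the within-set comparison of the trophectoderm list, the tests of the barcode set as whole cause and of shared reads for metallothioneins, the comparison of ribosomal protein genes by length, the test of pluripotency genes left at day 4, and the test of CGA and IGFBP5 in the same cells.

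In 23 genes of the lists, levels at 12 h or 24 h were at least 2-fold above both t0 and day 4. They included the BMP targets ID1 (130.0, 1408, 1516.5 and 450.0 CPM at t0, 12 h, 24 h and day 4), SMAD6, SMAD9 and BAMBI, and the primitive streak genes EOMES (1.38 at 12 h and 0 at day 4) and WNT3. GDF3 was at 58.8 CPM at 24 h and 0.111 at day 4. B2M, the light chain of HLA class I, was at 224, 292, 560 and 152 CPM over the same times and at 502 in TSC. EGLN3, a target of hypoxia signalling, was at 77.7 at 24 h, 17.5 at day 4 and 102 in TSC.

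A cluster of 36 TSC cells, 3.98% [2.80, 5.46], had ACTC1, SPP1, NNMT, ANKRD1 and HAND1 as leading genes. VTCN1 and IGFBP3 were among its markers, but a marker needed a UMI in only a small share of its cells. IGFBP3 had 11 UMIs in all TSC. Markers of other lists, such as LHX2, TUBB3, STMN2, CXCR4 and COL3A1, were among its markers too. Another cluster of 150 cells, 16.6% [14.2, 19.2], was defined by KISS1 and tubulin genes. Clusters of few UMIs were 136 cells at 12 h with a median of 1185.5 UMIs, 42 at t0 with 1653 and 75 at 24 h with 4414. A group of transcripts around CTNNB1, HNRNPH1, LRRC75A and C1orf56 defined clusters at t0, 12 h and 24 h. The share of cells above 4 UMIs of this group was 20.8% [19.5, 22.2] at t0, 47.2% [44.2, 50.2] at 12 h, 16.1% [14.9, 17.4] at 24 h, 18.4% [14.8, 22.4] at day 4 and 1.46% [0.778, 2.48] in TSC. For 3 explanations of this group, tests were written before their results were seen: shallow or damaged cells, RNA retained in the nucleus, and a property of the first barcode set. At 12 h the rank correlation of the group's UMIs was -0.47 with the UMI total, 0.06 with the mitochondrial share and 0.14 with the share of MALAT1 and NEAT1. At t0 the values were -0.27, 0.03 and 0.06, and at 24 h -0.15, 0.14 and 0.09. None of the 3 tests met its bounds in all the libraries it named, so all stay open, and the group was left out of the patterns weighed below after these results were seen.

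The trophectoderm list was 5.63 higher on the log2 scale at day 4 than at t0, in libraries with different barcode sets. Library chemistry as the whole cause is argued against by the median of 1.31 at 24 h over t0, inside 1 barcode set. A trend with transcript length is argued against by a median of 5.55 [5.39, 5.68] after the trend was taken off. Ribosomal protein ratios spread 1.23 [1.00, 1.5] times as widely at day 4 over 24 h (SD 0.711) as at 12 h over t0 (0.578). The interval is from resampled genes, as for the medians by length below. The pair 12 h over t0 was the widest of the 3 pairs inside a set that were named for the test. The value of 1.23 was short of the 2 times foreseen. Taken alone it met the bound foreseen without such effects, but its interval did not. The named pairs without t0 had far smaller SDs, 0.162 at 24 h over 12 h and 0.322 at TSC over day 4. The SD was 0.589 at 24 h over t0, also inside a set, and 0.869 and 0.879 across sets at day 4 and TSC over t0. The pairs with t0 held the difference in short mRNAs, and the 1.23 was taken against such a pair, while day 4 over 24 h holds no t0. Gene-specific effects of chemistry therefore stay open (the interval was added to the bounds after the value was seen). The share of MALAT1 and NEAT1, highest at day 4, was not tested as a cause, and in TSC, with a share of 0.53%, the list was 5.98 above t0. The stage itself stays open as an untested cause, and how much the set adds to a gene was not measured.

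Metallothioneins were at 982, 1343, 676, 3.99 and 864 CPM from t0 to TSC, summed over 10 genes. Chemistry as the whole cause is argued against by the median of 5.55 at TSC over day 4, inside 1 barcode set. Reads shared between copies are argued against by the sum, 169 times higher at 24 h than at day 4, and a loss of short transcripts by a median of -0.35 for other genes under 700 bases at day 4 over 24 h. In TSC, MT1E and MT2A were high and the other 5 members, picked because they were low there, were in the median at 0.0312 [0.0289, 0.0373] of t0. An effect of chemistry on those 5 was not tested and stays open, as do medium and stage, which differ between the same libraries.

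Short ribosomal protein mRNAs were lower at t0 than at 12 h, inside 1 barcode set. Other genes under 700 bases were higher at 12 h by 0.31 [0.20, 0.44] on the log2 scale, against genes of 1500 to 3000 bases, so a loss of short transcripts from the t0 library may be a part. Genes of 700 to 1500 bases were lowest, at -0.32 [-0.34, -0.30] against -0.21 for 1500 to 3000 bases and -0.06 for longer ones, so no loss graded by length was seen. A change of the ribosomal protein genes whatever their length is argued against by the 46 longer ones, whose median of 0.045 [-0.08, 0.12] stayed under that of the short ones, 0.72 [0.52, 1.05]. The value of 0.31 lay under the 0.5 foreseen for a loss of short transcripts and above the 0.1 foreseen without one, so it stays open, as does a change of the short ribosomal protein mRNAs alone. No biological explanation was tested.

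A hypothesis was that POU5F1 at day 4 came wholly from cells that did not start the change. The test planned for it was undecided: GATA3 was found in 70.4% [64.1, 76.2] of 233 day 4 cells with a POU5F1 UMI and 82.2% [76.2, 87.3] of 197 without, a ratio of 0.856 [0.767, 0.956] with the 0.8 set as the bound inside its interval, and free GATA3 RNA at day 4 was not measured. Such cells would keep other abundant transcripts of t0 at the share kept by POU5F1, 26.6% of its t0 level. Of 14 other pluripotency genes with at least 50 CPM at t0, 6 lay under that share by more than 3.34-fold (2 SD of the ribosomal protein ratios of the same pair), intervals included: NANOG (2.48%), TDGF1 (1.19%), SFRP2 (1.13%), USP44 (1.46%), TERF1 (4.59%) and LEFTY1 (1 UMI). The other 8 did not, and LIN28A, ZFP42 and SALL4 were above their t0 level. The 6 genes argue against such cells as the whole source, as far as chemistry, which differs with the barcode set here, did not lower them by more than that margin. A smaller part from such cells stays open.

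Another hypothesis was that amnion and syncytiotrophoblast genes lie in different day 4 cells. IGFBP5 was found in 12.5% [3.51, 29] of 32 cells with a CGA UMI and 30.2% [25.7, 34.9] of 398 without, 17.7 percentage points fewer. IGFBP3 was found in 56.3% [37.7, 73.6] and 67.3% [62.5, 71.9] of the same cells, and VTCN1 in 31.3% [16.1, 50.0] and 45.0% [40.0, 50.0]. The gap of 17.7 percentage points fell between the bounds set for the test. The intervals overlap, which is not itself a test of a difference. Separate cells may explain it, but the 32 cells found after thinning did not decide it. Among the day 4 clusters, CGA was the lowest gene of the amnion-like one and IGFBP5 among the lowest of the syncytiotrophoblast-like one. Such genes define the clusters, so this is no separate evidence.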
